A study of Danio rerio with 18 samples.

How the data were processed

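Whole-embryo total RNA from control and troponin T2 morphant zebrafish embryos was measured on 18 Affymetrix zebrafish arrays, 3 for each kind of embryo at 36, 48 and 60 hours after fertilisation. Groups and array numbers were taken from the sample titles. Per the labels' protocols, morpholinos were injected at the 1-cell stage, and RNA was purified with Trizol and RNeasy columns. No columns of other samples were present.

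The deposited series values are expression values of 15617 probe sets per array on a log2 scale. Per the deposited readme, expression was estimated with the puma package, and the file names give mmgMOS, a probe-level model that returns a value and its standard error. The version of puma is not given in the sources used here. The deposited files do not state the base of the logarithm. It was taken as log2, the scale that mmgMOS returns. The deposited standard errors are on the same log2 scale. For each group the authors combined the 3 arrays with pumaComb, and with pumaDE they gave log2 ratios of morphant over control and a probability of a positive log ratio, from 0 to 1, per the deposited readme. In the deposited table of combined values for all 6 groups no value was below 0. The authors' lists of higher and lower probe sets were used for gene names and for 1 comparison. In their list of higher probe sets at 60 hours, 0 of 24 names that could be checked matched their probe set, so the names of that sheet were not used.

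Array medians of the deposited log2 values spanned 2.68, over the limit of 0.1 fixed for values normalised between arrays. Control probe sets of the manufacturer (115) were left out, and the other 15502 were quantile normalised with limma. Probe sets with a mean under the 25th percentile (0.62 on the log2 scale) were left out, which left 11626. Array values have no counts, so the number of arrays limits the precision, and the median standard error of a difference at 1 time was 0.28.

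Gene names were taken from descriptions in the deposited tables, from symbols in the deposited lists and from a RefSeq gene table of assembly GRCz12tu, which was used for names only. Accessions, clone names, UniGene and Entrez numbers and 47 aliases written by hand linked probe sets to genes. This gave 4156 probe sets with 1 name, 21 with several and 11325 with none, for 3520 genes. Of 1503 probe sets with names from more than 1 source, 1456 had a name shared by all sources. Where the name in a deposited list conflicted with every other source, the probe set was left unnamed, a step taken after the results had been seen. For 197 probe sets a deposited list was the only source of the name. Of the tested probe sets 3323 had a name, for 2877 genes.

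Differences were tested with limma (version 3.58.1, R 4.3.3). A mean was fitted for each of the 6 groups on all 18 arrays, with no covariate and no replicate term, and contrasts were tested with moderated statistics and an intensity trend (12 residual and 6.24 prior degrees of freedom). The contrasts were morphant minus control at each time, their average, the F-test of the difference between times, and 60 minus 36 hours within each kind of embryo with its 2 steps. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and adjusted p under 0.05 was the threshold. Fold values are powers of the log2 differences, and none is given where the mean of a group compared lay under 0.62, since values that dim do not fix the size of a change.

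Of 33 gene lists fixed for tissues, cell types and pathways, 30 had at least 4 measured genes and were tested with limma's camera, with a preset correlation of 0.01 between genes, an estimated correlation beside it, and adjustment over the lists. Each gene was represented by the probe set with the highest mean. Genes were also adjusted over their list alone. The shift along development was the least-squares slope, across probe sets, of the difference between morphants and controls on a control change between times measured on other arrays (60 minus 48 hours for the 36-hour difference, 60 minus 36 for 48 hours, 48 minus 36 for 60 hours). It was tested by all 8000 relabellings within times, two-sided.

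The genes named were fixed by rule. They were tnnt2a, up to 10 higher and 10 lower named genes with the largest called difference at each time, on average and in control development, and up to 4 members of each list past the threshold. At single times all 3 morphant arrays had to lie on one side of all 3 control arrays, and for the average in at least 2 times. The 10 genes with the smallest p for a difference between times were added, together with a fixed set (klf2a, vegfaa, myl7, kdrl, cxcr4a and the brightest embryonic globin, and hmox1a, nppa, vmhc, cdkn1a and nos2a, which had no named probe set). One further gene of that set and 1 of the 30 lists tested, which passed at 36 hours and on average and is counted there, are not reported here. Other called members of the lists were named after their values were seen. The design, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

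The tests were tried on simulated data first, with 200 of 11626 probe sets changed in arrays drawn with the real means and spreads. At log2 changes of 0.5, 1, 2 and 3, the test recovered 8%, 42%, 74% and 96% at 36 hours, 10%, 44%, 76% and 96% at 48 hours, 6%, 40%, 84% and 96% at 60 hours, and 36%, 70%, 96% and 100% on average. Of 11390 unchanged probe sets 7, 7, 8 and 8 were called. The F-test between times recovered 81% of changes of 3 with 5 false calls. The simulated noise was independent between probe sets and alike on all arrays, with no difference in brightness and no pairing. The real arrays had quality weights from 0.127 to 4.02, so these rates need not hold for them.

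Alternatives covered the normalisation (values as deposited, or centred on array medians), the filter, the variance trend, weights from the deposited standard errors, leaving out each array, a replicate block, fitting only the arrays compared, a minimum log2 difference of 1, 1 probe set per gene, and the correlation and the probe sets used for lists. Added after the data were seen were array quality weights, the array median as a covariate, leaving out the 2 arrays with the lowest medians, leaving out 36 hours, leaving the retina list out of the developmental shift, leaving out names that only the authors' lists give, tests of list differences between times, and swaps of labels only within same-numbered pairs for the developmental shift. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.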

Results

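Gene expression was measured in whole zebrafish embryos on an Affymetrix zebrafish array. Embryos had been injected at the 1-cell stage with a morpholino, a synthetic antisense oligonucleotide, against cardiac troponin T2, a heart muscle protein without which the heart does not beat, and were compared with control embryos. Total RNA was taken 36, 48 and 60 hours after fertilisation, which gave 6 groups of 3 arrays, and the small number of arrays limits the precision of every comparison. The sample titles call the controls wild type while the design text names a control morpholino, so they are called control embryos here. One protocol gives 32 hours where the titles give 36, and the titles' time is used. The p-values measure only the spread between these arrays, since the labels do not say whether the 3 RNA samples of a group came from separate clutches or injections.

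As deposited, the arrays differed in brightness. Their median log2 values ran from 1.19 to 3.86, and the mean median of the morphants minus that of the controls was 0.30 at 36 hours, -0.69 at 48 hours and 0.50 at 60 hours. The values were therefore quantile normalised, and every difference given here is relative to the other probe sets of the same array. Of 15502 probe sets, 4156 carried 1 gene name, so most called probe sets could not be named.

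**Figure D1:**
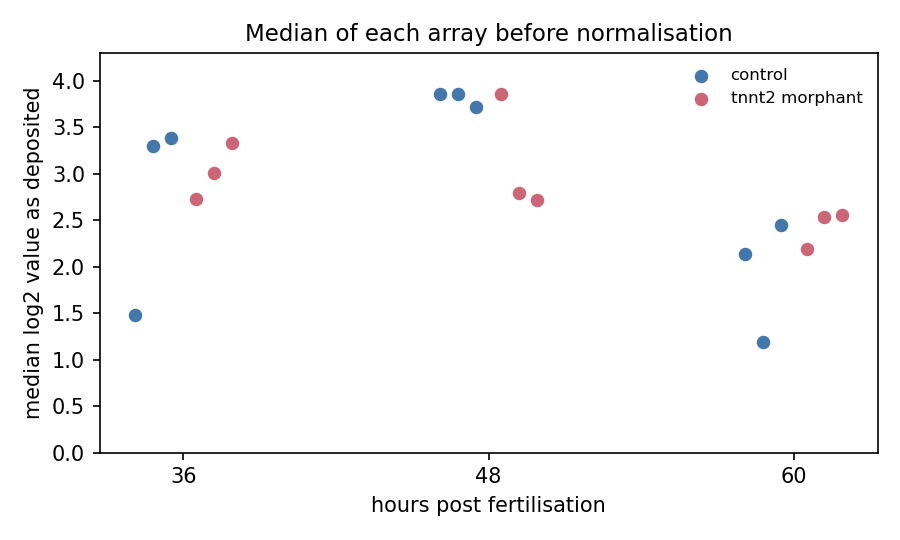
Median log2 value of each of the 18 arrays before normalisation, by hours after fertilisation, with control arrays and troponin T2 morphant arrays in separate colours and 1 point per array. The medians span 2.68 log2 units, from 1.19 in a control array of 60 hours to 3.86 in a morphant array of 48 hours.

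The targeted gene, tnnt2a (Dr.14260.1.S1_a_at), did not differ past the threshold between the kinds of embryo at any time. In control embryos its log2 level was 2.03 ± 1.16 at 36 hours, 3.23 ± 0.20 at 48 hours and 2.53 ± 0.36 at 60 hours (mean ± SD, n = 3 arrays). In morphants it was 2.01 ± 0.46, 3.21 ± 0.22 and 2.22 ± 0.82 at the same times. The differences were -0.02, -0.02 and -0.31, each with a standard error of 0.47, and none passed the test (limma adjusted p = 0.992, 0.999 and 0.744). The labels do not say whether the morpholino blocks translation or splicing, so the level of the transcript does not check the knockdown.

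The comparison at 36 hours asks which transcripts had changed at the earliest time sampled. Genes of the sterol synthesis list were higher in the morphants, and single genes of the forming retina were lower. The sterol C4-demethylase gene msmo1 (Dr.12110.1.S1_at) rose by a log2 difference of 3.13 ± 0.55 (SE, n = 3 arrays per group, limma adjusted p = 0.0219). Its control mean lay under 0.62, too dim to fix the size of the rise. The gene of the sterol-sensing protein insig1 (Dr.26534.1.A1_at) rose 3.37-fold, by 1.75 ± 0.21 (limma adjusted p = 0.00168), and its other 2 probe sets rose as well. Transcripts of crx (Dr.14325.1.S1_at), a transcription factor that switches on photoreceptor genes, fell by 4.69 ± 0.75 (limma adjusted p = 0.0104). Its log2 level was between 0.28 and 2.12 in the control arrays and between -5.95 and -1.09 in the morphant arrays, too dim to fix the size of the fall.

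In all, 21 of 11626 probe sets passed at 36 hours, 11 higher and 10 lower, and 11 of them had a name. Besides msmo1 and insig1, the named genes that rose included scarb2a, which encodes a lysosomal membrane protein, by 1.42 ± 0.27 (limma adjusted p = 0.0300), and ube2d3, a ubiquitin-conjugating enzyme, by 0.64 ± 0.11 (limma adjusted p = 0.0165). The photoreceptor nuclear receptor gene nr2e3 fell by 3.21 ± 0.57 (limma adjusted p = 0.0234), a call that was lost without control array 1 or control array 2 (limma adjusted p = 0.0893 and 0.0611). That of scarb2a was lost without any one of control arrays 1 and 2 and the morphant arrays (limma adjusted p from 0.0525 to 0.147). The keratin gene krt15 fell by 2.84 ± 0.43 (limma adjusted p = 0.00714).

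Of 30 gene lists tested with limma's camera at 36 hours, 5 passed, among them those for sterol synthesis, retina, cell cycle and epidermis. The sterol synthesis list had 29 genes, of which 6 were measured. Among these 6, 2 rose and 4 were not past the threshold over all probe sets, while 4 rose adjusted over the list alone (median 1.47, adjusted p = 2.81e-07). Among the members that did not pass, fdps had a difference of 1.19 ± 0.24 (limma adjusted p = 0.0512) and hmgcs1 one of 1.89 ± 0.61 (limma adjusted p = 0.245). The photoreceptor and retina list was lower, with 1 of 13 genes fallen and 3 adjusted over the list alone (median -1.06, adjusted p = 2.20e-05), but its adjusted p was 0.0997 with an estimated correlation. Of its members that did not pass, rpe65a, a visual cycle enzyme, differed by -2.26 ± 0.57 (limma adjusted p = 0.151). The list of cell cycle and DNA replication genes was lower as a group with no single gene past the threshold, also adjusted over the list alone (24 genes, median -0.23, adjusted p = 0.00747). Its members ccna2, pcna and rpa1 differed by -0.57, -0.22 and -0.39, and the list had an adjusted p of 0.612 with an estimated correlation. Epidermis and ionocyte genes were higher as a group, with 0 of 14 genes called and 1 adjusted over the list alone (median 0.25, adjusted p = 0.00747). That list had an adjusted p of 0.282 with an estimated correlation, and with each array only centred on its median its direction turned (adjusted p = 0.940). The antiproliferative gene btg2 differed by 0.83 ± 0.19 and was not past the threshold (limma adjusted p = 0.0947).

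Some of the names come from the authors' own lists, which were drawn up on these arrays: insig1 and cyp51 in the sterol list, rpe65a and rcvrn2 in the retina list, krt1-19d in the epidermis list, itih3a.1 in the liver list, matn1 in the cartilage list and sncgb in the neuron list. Members named in this way are not independent evidence of direction. For insig1 only the probe set used depends on the lists, since the array descriptions of its other probe sets name the INSIG-1 protein. The naming step missed that wording, so leaving insig1 out is strict for that gene. With those names left out, the sterol list kept 4 genes and had 1 rise at 36 hours (median 1.54, adjusted p = 5.36e-05), with an adjusted p of 0.0896 with an estimated correlation. The retina list then kept 11 genes, 1 of them fallen (median -0.87, adjusted p = 4.07e-04, and adjusted p = 0.191 with an estimated correlation). No probe set passed at 36 hours on the values as deposited (limma, 244 at an unadjusted p under 0.05) or with the 6 arrays of that time alone (627 at an unadjusted p under 0.05). The count was 293 without control array 3 of that time, 12 without morphant array 1 and 13 without morphant array 2, and msmo1 lost its call without either of those morphant arrays (limma adjusted p = 0.0936 and 0.107).

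At 48 hours the sterol genes were again higher, as was the list for the amino acid starvation response, and the retina genes were again lower. The methylsterol enzyme gene msmo1 rose 13.4-fold, by 3.75 ± 0.55 (SE, n = 3 arrays per group, limma adjusted p = 0.00244). Transcripts of hmgcs1 (Dr.2051.1.S1_at), which encodes an early enzyme of the pathway, rose 10.9-fold, by 3.45 ± 0.61 (limma adjusted p = 0.0102). The fatty acid desaturase gene fads2 rose by 3.42 ± 0.55 (limma adjusted p = 0.00523), and rasd1, a Ras-related small GTPase gene, rose by 3.63 ± 0.36 (limma adjusted p = 8.31e-05). The chemokine receptor gene cxcr4a, which is expressed in endothelium and lies in the flow-responsive list, rose by 2.78 ± 0.42 (limma adjusted p = 0.00292).

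At this time 66 probe sets passed, 43 higher and 23 lower, and 34 of them had a name. The lanosterol demethylase gene cyp51 (Dr.1603.1.A1_x_at) rose by 4.24 ± 0.91 (limma adjusted p = 0.0461), and the type I keratin gene krt1-19d by 4.19 ± 0.50 (limma adjusted p = 7.38e-04). The receptor phosphatase gene ptpra, the BMP receptor gene bmpr1aa and the phosphatase regulatory subunit gene ppp1r13ba rose by 3.23 ± 0.45, 3.22 ± 0.71 and 2.73 ± 0.35. Among the genes that fell were firrm, which takes part in DNA repair, by 2.45 ± 0.38 (limma adjusted p = 0.00377), and the transcription factor gene cebp1, by 2.36 ± 0.44 (limma adjusted p = 0.0194). The genes chid1, rnf25 and leo1 fell by 2.36 ± 0.53, 1.86 ± 0.31 and 0.75 ± 0.15.

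Of the gene lists, 6 passed at 48 hours. All but 1 of the 6 sterol genes rose, and all 6 adjusted over the list alone (median 2.44, adjusted p = 1.53e-13). Farnesyl diphosphate synthase, fdps, rose by 1.43 ± 0.24 and insig1 by 0.97 ± 0.21 (limma adjusted p = 0.00827 and 0.0471). Without the names from the authors' lists, 3 of the 4 remaining sterol genes rose (adjusted p = 1.23e-09). Of 13 targets of ATF4, the transcription factor of the amino acid starvation response, 2 rose and 7 adjusted over the list alone (median 0.50, adjusted p = 9.34e-08). They were igfbp1a, a secreted protein that binds insulin-like growth factors, by 1.54 ± 0.26 (limma adjusted p = 0.00842), and asparagine synthetase, asns, by 2.5 ± 0.54 (limma adjusted p = 0.0461). Neither is particular to this list, since igfbp1a also lies in those for hypoxia and gluconeogenesis and asns in that for heat shock. The member ddit4 is shared with the hypoxia list. In the photoreceptor and retina list no gene passed over all probe sets and 5 of 13 were lower adjusted over the list alone (median -0.69, adjusted p = 1.87e-06). Its members vsx1, rcvrn2 and rx1, all genes of the eye, differed by -0.69, -2.66 and -1.03. Without the names from the authors' lists it kept 11 genes (adjusted p = 9.97e-06, and adjusted p = 0.0518 with an estimated correlation).

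The interferon, complement and inflammation list was higher as a group at 48 hours, with 0 of 11 genes called and 3 adjusted over the list alone (median 0.64, adjusted p = 4.06e-04). Its adjusted p was 0.0603 with an estimated correlation, and its members b2m and mmp9 differed by 1.71 and 1.39. Erythroid genes were higher as a group, with 0 of 17 called and 3 adjusted over the list alone (median 0.20, adjusted p = 0.0282), but with an adjusted p of 0.197 with an estimated correlation. The haem synthesis genes urod and hmbsa in it differed by 0.75 and 0.88. Cytosolic ribosomal protein genes were higher as a group by a median of 0.07, with 0 of 18 called, also adjusted over the list alone (adjusted p = 0.0302), and with an adjusted p of 0.317 with an estimated correlation. Without control array 2 or morphant array 3 of this time, the erythroid list (adjusted p = 0.218 and 0.105) and the ribosomal list (adjusted p = 0.204 and 0.108) were not past the threshold.

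The number of probe sets called at 48 hours was 5 on the values as deposited, 1 higher and 4 lower. It was 21 without control array 1, 29 without control array 2, 32 without morphant array 2 and 21 without morphant array 3, and hmgcs1 lost its call without any one of these (limma adjusted p from 0.0555 to 0.0650). The genes cyp51 and asns lost theirs without any one of the 6 arrays (limma adjusted p from 0.0563 to 0.217).

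At 60 hours single photoreceptor genes passed as lower, and sterol genes were again higher. The ultraviolet cone opsin gene opn1sw1 (Dr.8194.1.S1_at) fell by 4.37 ± 0.70 (SE, n = 3 arrays per group, limma adjusted p = 0.00896), and the blue cone opsin gene opn1sw2 fell 3.83-fold, by 1.94 ± 0.32 (limma adjusted p = 0.0102). The morphant mean of opn1sw1 lay under 0.62, too dim to fix the size of its fall. Among the sterol genes, fdps rose 4.12-fold, by 2.04 ± 0.24 (limma adjusted p = 5.40e-04), and insig1 3.02-fold, by 1.6 ± 0.21 (limma adjusted p = 0.00170). The embryonic beta globin gene hbbe3 (DrAffx.2.19.S1_at) rose 2.83-fold, by 1.5 ± 0.15 (limma adjusted p = 7.66e-05).

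In total, 107 probe sets passed at 60 hours, 79 higher and 28 lower, with 41 named. Genes that rose included fosl2, an AP-1 transcription factor gene, by 2.96 ± 0.66, and gnmt, a glycine methyltransferase gene, by 1.97 ± 0.30 (limma adjusted p = 0.0441 and 0.00646). Also higher were hmgcs1 by 2.73 ± 0.61, msmo1 by 2.72 ± 0.55, the red cell membrane skeleton gene epb41b by 2.2 ± 0.45, rasd1 by 1.74 ± 0.36, scarb2a by 1.64 ± 0.27 and dnajc5gb by 2.43 ± 0.56. The cardiac myosin light chain gene myl7 rose by 0.68 ± 0.15 (limma adjusted p = 0.0453). Genes that fell included ckmt2a, a mitochondrial creatine kinase gene, by 2.73 ± 0.60, and elovl4b, a fatty acid elongase gene, by 1.93 ± 0.33 (limma adjusted p = 0.0407 and 0.0109). The eye field gene rx2 fell by 1.93 ± 0.38, gng13b by 1.77 ± 0.41, eipr1 by 1.25 ± 0.28, bhlhe22 by 0.92 ± 0.17 and the synaptic gene snap25b by 0.74 ± 0.17.

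Of the gene lists, 5 passed at 60 hours. In the photoreceptor and retina list 4 of 13 genes fell and 8 adjusted over the list alone (median -1.93, adjusted p = 1.06e-07), among them vsx1, a bipolar cell transcription factor gene, by 1.05 ± 0.19. Of the 6 sterol genes 4 rose and 5 adjusted over the list alone (median 1.82, adjusted p = 1.06e-07). Without the names from the authors' lists, 3 of 4 sterol genes rose (adjusted p = 4.28e-06) and 4 of 11 retina genes fell (adjusted p = 1.09e-06). Of 13 ATF4 targets 2 rose and 3 adjusted over the list alone (median 0.47, adjusted p = 3.52e-04), and the list had an adjusted p of 0.174 with an estimated correlation. They were igfbp1a by 1.66 ± 0.26 and psat1, an enzyme of serine synthesis, by 1.02 ± 0.17 (limma adjusted p = 0.00896 and 0.0109).

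Among 17 erythroid genes at 60 hours, 3 rose and 4 adjusted over the list alone (median 0.10, adjusted p = 0.0477). They were hbbe3, urod by 1.13 ± 0.20 and epb41b, and the list had an adjusted p of 0.214 with an estimated correlation. It was not past the threshold without control array 1 (adjusted p = 0.0669), control array 3 (0.0837) or morphant array 1 (0.109). The replicate block of same-numbered arrays ended its call as well. Of 14 epidermis genes 1 rose and 3 adjusted over the list alone (median 0.25, adjusted p = 0.00553), with an adjusted p of 0.214 with an estimated correlation. The list was not past the threshold on the values as deposited (adjusted p = 0.253), with arrays centred on their medians (0.961) or with all probe sets of its members (0.0600). The gene called was the keratin gene cyt1, by 0.42 ± 0.08 (limma adjusted p = 0.0197), but 1 of its 4 other probe sets had the opposite sign, and with arrays only centred on their medians its difference was -0.0556 (limma adjusted p = 0.948).

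The count at 60 hours was 1 on the values as deposited. Leaving out 1 array gave 28 without control array 1, 14 without control array 2, 456 without control array 3, 350 without morphant array 1, 10 without morphant array 2 and 14 without morphant array 3, and opn1sw1 lost its call without control array 2 (limma adjusted p = 0.0642). The genes msmo1 and hmgcs1 lost theirs without control array 2, morphant array 2 or morphant array 3 (limma adjusted p from 0.0910 to 0.190), as did myl7, which also lost it without control array 1 (limma adjusted p from 0.0789 to 0.220).

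**Figure D2:**
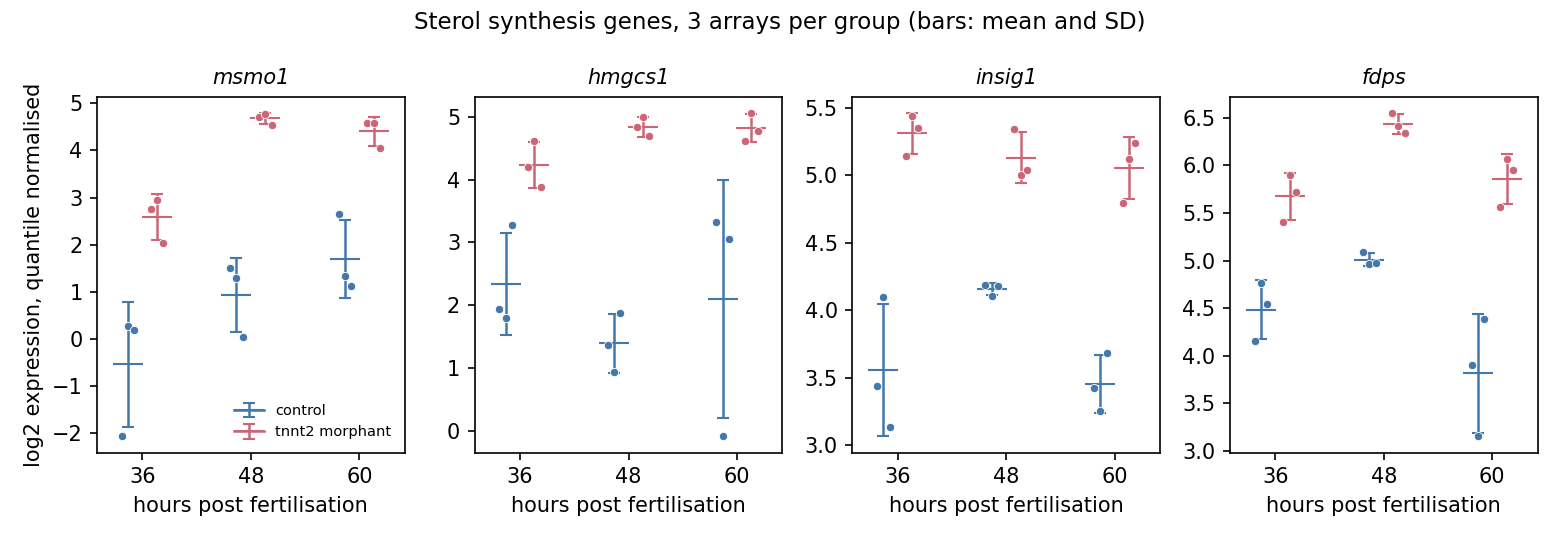
Quantile-normalised log2 expression of msmo1, hmgcs1, insig1 and fdps, members of the sterol synthesis list, against hours after fertilisation, with points for single arrays and bars for the mean and SD of 3 control (blue) or 3 morphant (red) arrays. Of these, insig1 encodes a sterol-sensing protein and not an enzyme. For msmo1 the morphant means were 2.58, 4.68 and 4.41 at 36, 48 and 60 hours, against -0.54, 0.94 and 1.69 in control embryos.

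Averaged over the 3 times, with 9 arrays of each kind, the morphants had higher sterol synthesis genes and lower photoreceptor genes. All 6 sterol genes measured rose, msmo1 by 3.20 ± 0.32 (SE), hmgcs1 by 2.69 ± 0.35 and fdps by 1.55 ± 0.14 (limma adjusted p = 1.65e-05, 2.85e-04 and 5.16e-06). Of 13 photoreceptor and retina genes 8 fell, opn1sw1 by 2.43 ± 0.40, crx by 2.41 ± 0.43 and the rod opsin gene rho by 1.57 ± 0.39 (limma adjusted p = 0.00232, 0.00446 and 0.0271). The growth factor gene vegfaa, a driver of vessel growth and a target of hypoxia signalling, rose 2.45-fold, by 1.30 ± 0.27 (limma adjusted p = 0.0116). The transcription factor gene klf2a, which responds to blood flow in endothelium, fell by 0.59 ± 0.13 (limma adjusted p = 0.0196, and 0.0527 without morphant array 2 of 60 hours).

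On average 559 probe sets passed, 286 higher and 273 lower, of which 197 were named and 532 had the same sign at all 3 times. All 3 morphant arrays lay on one side of all 3 control arrays for 334 of them at 36 hours, 402 at 48 hours and 380 at 60 hours. Over all probe sets tested that held for 13.9%, 24.9% and 20.2%, where chance gives 10%. The 559 were chosen by the average of the same differences, which favours equal signs and separation. Those shares are therefore no reference for them. Further genes that rose were fads2 by 2.53 ± 0.32, rasd1 by 2.12 ± 0.21, gnmt by 1.61 ± 0.17, the neuronal nitric oxide synthase gene nos1 by 1.78 ± 0.37, cxcr4a by 1.48 ± 0.24, bmpr1aa by 1.86 ± 0.41 and fam49a by 1.6 ± 0.38. Further genes that fell were nr2e3 by 1.81 ± 0.33, gngt2a, a cone transducin subunit gene, by 2.01 ± 0.44, rx3, an eye field gene, by 1.38 ± 0.29, the adrenergic receptor gene adra2da by 1.74 ± 0.40, chid1 by 1.73 ± 0.30, itih3a.1 by 1.86 ± 0.46 and slc9a8 by 1.29 ± 0.33.

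Of the gene lists, 7 passed on average, among them those for sterol synthesis, retina, ATF4 targets, epidermis, interferon and cell cycle. The sterol list was higher (6 of 6 risen, 6 adjusted over the list alone, median 1.84, adjusted p = 2.64e-11), with cyp51, insig1 and acat2 up by 2.13 ± 0.53, 1.44 ± 0.12 and 0.47 ± 0.11. The photoreceptor and retina list was lower (8 of 13 fallen, 10 adjusted over the list alone, median -1.11, adjusted p = 1.22e-10), with rcvrn2, gnat2, rx2, opn1sw2 and vsx1 down by 2.13, 1.5, 1.06, 1.0 and 0.71. Without the names from the authors' lists, 4 of 4 sterol genes rose (adjusted p = 2.71e-08) and 7 of 11 retina genes fell (adjusted p = 8.00e-09). Of 13 ATF4 targets 5 rose and 9 adjusted over the list alone (median 0.41, adjusted p = 2.07e-05), and the list had an adjusted p of 0.114 with an estimated correlation. With an estimated correlation the sterol list remained past the threshold at every time and on average, the retina list at 48 and 60 hours and on average, and the ATF4 list at 48 hours. The ATF4 targets that rose were igfbp1a by 1.29 ± 0.15, psat1 by 0.59 ± 0.10, the amino acid transporter gene slc3a2b by 0.46 ± 0.11, asns by 1.24 ± 0.31 and stc2a by 1.14 ± 0.29.

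Of 14 epidermis genes 3 rose on average and 4 adjusted over the list alone (median 0.17, adjusted p = 9.89e-04), with an adjusted p of 0.139 with an estimated correlation, 0.0791 on the values as deposited and 0.202 with arrays centred on their medians. They were the keratin genes krt1-19d, krt18a.1 and cyt1, by 1.45 ± 0.29, 0.25 ± 0.07 and 0.30 ± 0.05, but krt1-19d differed by -1.08 at 60 hours and 2 of 4 other cyt1 probe sets had the opposite sign. Of 11 interferon and inflammation genes the matrix metalloproteinase gene mmp9 rose, by 1.08 ± 0.27, and 2 rose adjusted over the list alone (median 0.48, adjusted p = 0.00316, and adjusted p = 0.139 with an estimated correlation). Of 24 cell cycle genes the cyclin gene ccna2 fell, by 0.47 ± 0.12, and 2 fell adjusted over the list alone (median -0.16, adjusted p = 0.00692, and adjusted p = 0.507 with an estimated correlation). The cell cycle list was not past the threshold without morphant array 3 of 60 hours (adjusted p = 0.0659). The gene btg2 rose by 0.83 ± 0.11 on average (limma adjusted p = 2.85e-04).

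**Figure D3:**
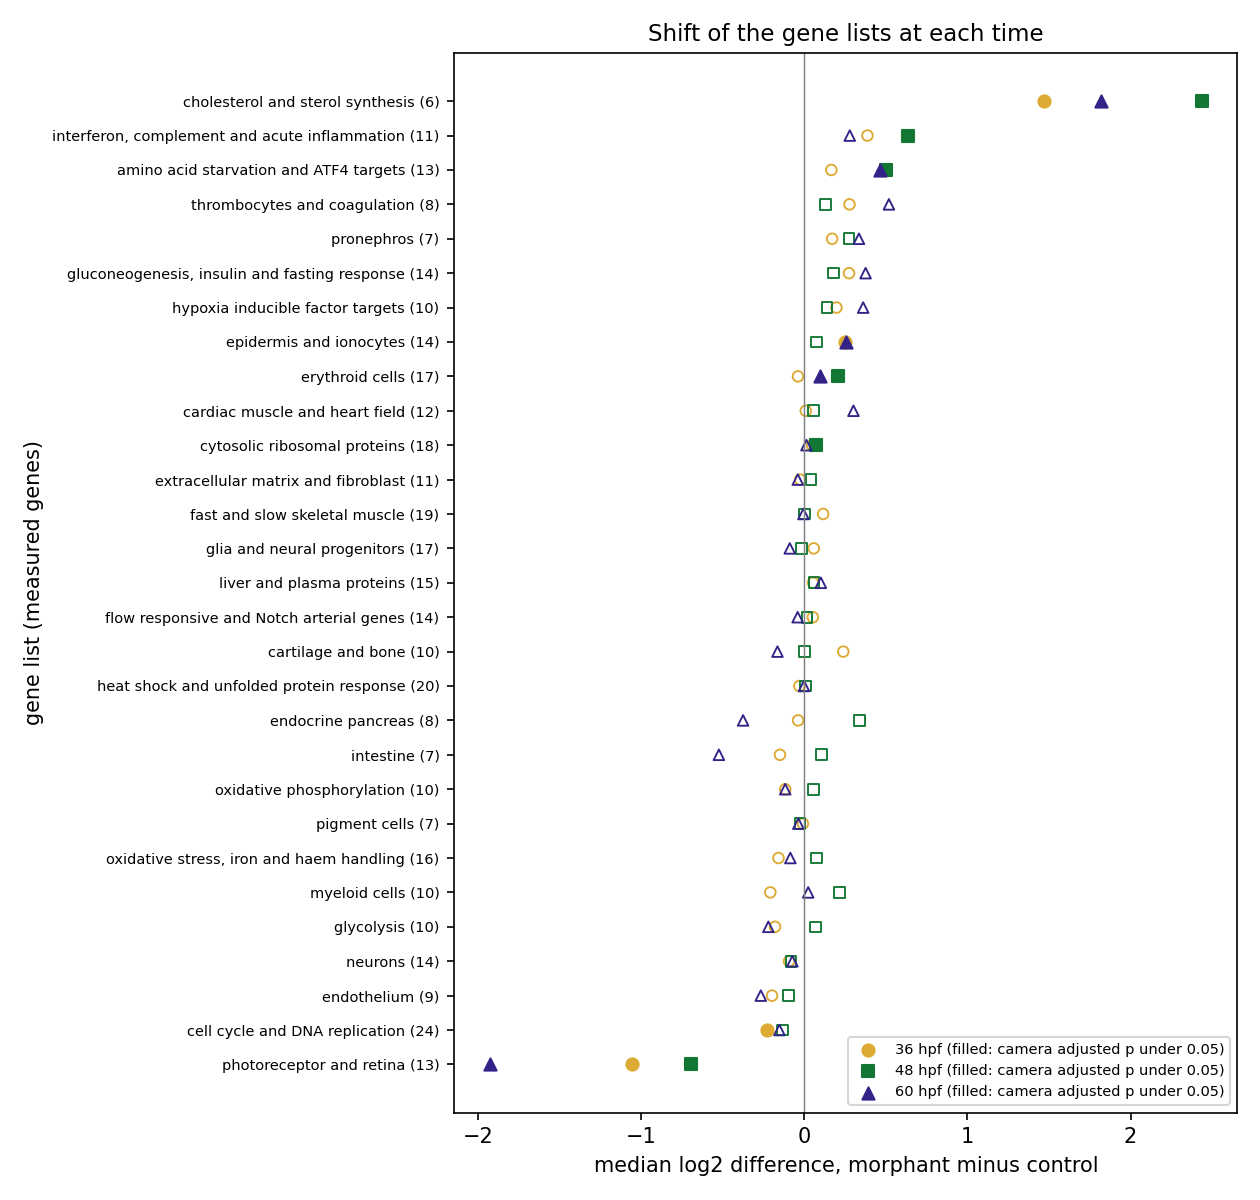
Median log2 difference, morphant minus control, of the measured genes of each of 29 lists at 36, 48 and 60 hours, with 1 point per list and time and filled points where camera's adjusted p was under 0.05. The sterol list had medians of 1.47, 2.44 and 1.82 and the photoreceptor and retina list -1.06, -0.69 and -1.93, while the epidermis list at 36 hours turned its direction under median centring.

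The other lists were not past the threshold on average, including those for the heart, vessels and blood. Only part of each was measured: 12 of 34 cardiac, 14 of 32 flow-responsive, 9 of 34 endothelial, 10 of 35 hypoxia and 17 of 35 erythroid genes. They therefore do not test a tissue or pathway as a whole. Of 12 cardiac muscle and heart field genes 2 rose, myl7 by 0.45 ± 0.09 and the transcription factor gene mef2ca by 1.34 ± 0.32 (list median 0.09, adjusted p = 0.236). Of 14 flow-responsive and arterial genes 2 rose, nos1 and cxcr4a, and 1 fell, klf2a (median 0.01, adjusted p = 0.751). None of 9 endothelial genes passed (median -0.14, adjusted p = 0.261), and the receptor gene kdrl differed by -0.07 ± 0.14 (limma adjusted p = 0.765). Of 10 hypoxia targets 3 rose, vegfaa, igfbp1a and higd1a (median 0.21, adjusted p = 0.0664), and igfbp1a is also in the ATF4 list. The erythroid list had 3 genes risen and 1 fallen of 17 (median 0.11, adjusted p = 0.0796), with hbbe3 up by 0.63 ± 0.09, urod by 0.69 ± 0.12 and epb41b by 1.17 ± 0.26, and the globin gene hbbe2 down by 0.34 ± 0.08. The brightest globin probe set, hbbe1.1, differed by -0.02, and by 0 at 48 and 60 hours, where it had the same value on every array and quantile normalisation leaves no difference to see.

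Medians and adjusted p-values of the remaining lists were as follows. Gluconeogenesis had 0.24 (0.0677), pronephros 0.26 (0.0912), ribosomal proteins 0.05 (0.110), oxidative phosphorylation -0.06 (0.182), thrombocytes and coagulation 0.33 (0.254), neurons -0.12 (0.261) and intestine -0.04 (0.315). Skeletal muscle had 0.04 (0.447), oxidative stress and iron -0.08 (0.447), glycolysis -0.09 (0.602), cartilage and bone -0.01 (0.602), myeloid cells -0.09 (0.717), glia and neural progenitors 0.03 (0.751) and pigment cells -0.08 (0.761). For extracellular matrix (median 0.04, mean -0.05, adjusted p = 0.788), liver (median 0.02, mean -0.12, 0.813), endocrine pancreas (median -0.03, mean 0.09, 0.893) and heat shock genes (median -0.02, mean 0.09, 0.974) the median and the mean had opposite signs. The test pointed down for matrix and endocrine pancreas and up for liver and heat shock genes. Lists for epicardium and valve, exocrine pancreas and lens had 2, 3 and 2 measured genes, under the 4 required, and were not tested.

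On the values as deposited 6 probe sets passed on average. With 1 array left out the average gave from 230 probe sets, without morphant array 2 of 60 hours, to 1551, without control array 3 of 36 hours.

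**Figure D4:**
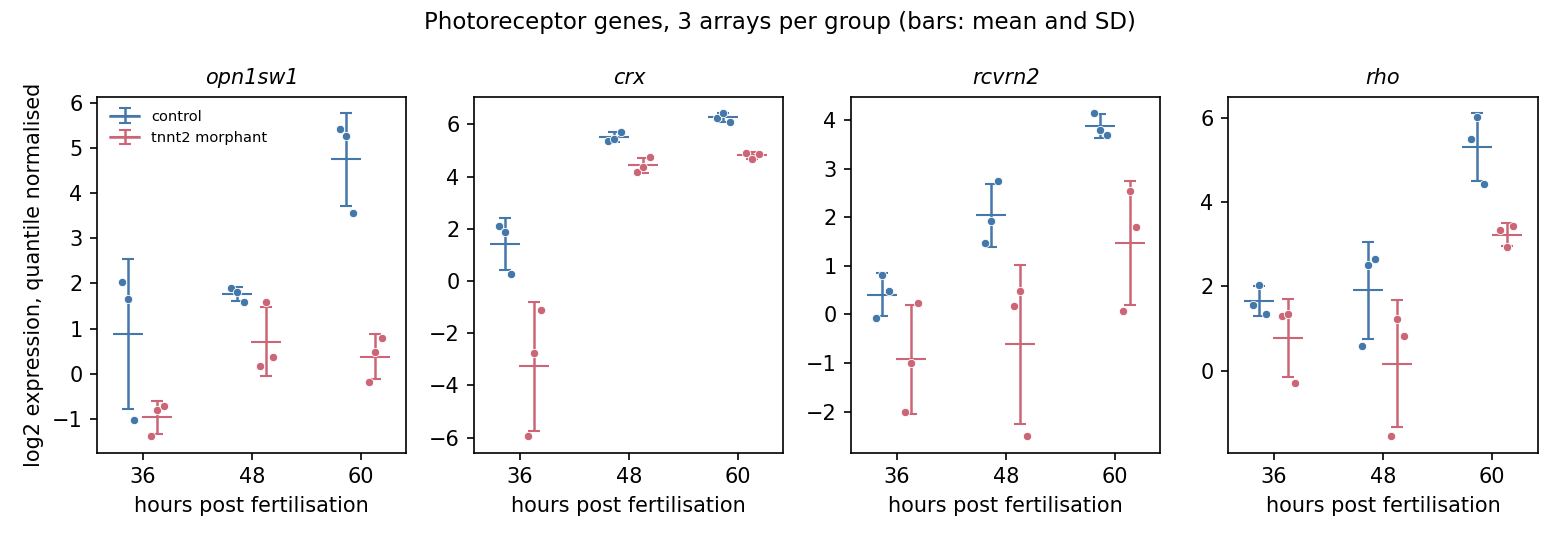
Quantile-normalised log2 expression of the photoreceptor genes opn1sw1, crx, rcvrn2 and rho against hours after fertilisation, with points for single arrays and bars for the mean and SD of 3 control (blue) or 3 morphant (red) arrays. At 60 hours opn1sw1 was between 3.56 and 5.43 in the control arrays and between -0.17 and 0.80 in the morphant arrays.

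Whether the difference between morphants and controls changed with time was tested probe set by probe set. It passed for 3 probe sets (limma's F-test, 899 at an unadjusted p under 0.05), a globin gene and a pair of keratin genes. For hbbe3 the difference was -0.08 at 36 hours, 0.46 at 48 hours and 1.5 at 60 hours (SE 0.15 each, limma adjusted p = 0.0179). Its level in control embryos went from 9.34 through 8.24 to 6.80, and in morphants from 9.26 through 8.71 to 8.30. The difference in krt1-19d was 1.23, then 4.19, then -1.08 (SE 0.50 each, limma adjusted p = 0.0179), and that in krt15 was -2.84, then 1.51, then -1.0 (SE 0.43 each, limma adjusted p = 0.0180). The next genes, fabp2, ptpra, rasd1, ppp1r13ba, orc5, gnmt and b2m, did not pass (limma adjusted p from 0.0728 to 0.286). All 3 calls were lost on the values as deposited, without the intensity trend and without control array 1, morphant array 1 or morphant array 2 of 48 hours, or control array 1, morphant array 1 or morphant array 2 of 60 hours.

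**Figure D5:**
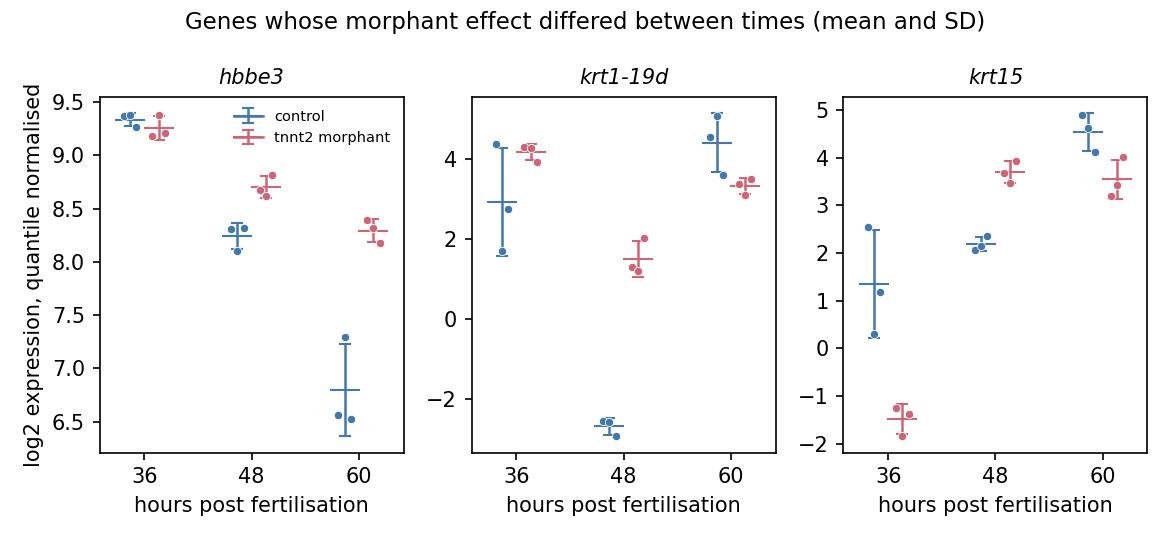
Quantile-normalised log2 expression of hbbe3, krt1-19d and krt15 against hours after fertilisation, with points for single arrays and bars for the mean and SD of 3 control (blue) or 3 morphant (red) arrays. In control embryos hbbe3 went from 9.34 to 6.80 between 36 and 60 hours, and in morphants from 9.26 to 8.30.

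The calls at single times overlapped, and no array is shared between times, but the times share 1 estimate of the spread per probe set, so the overlap of independent lists is no exact reference. Sterol genes made up most of the 5 probe sets called at all 3 times, which were msmo1, the 3 probe sets of insig1 and the unnamed Dr.21698.1.A1_at. Both 36 and 48 hours called 6 probe sets higher, where independent lists would share 0.0407. Both 36 and 60 hours called 6 higher and 2 lower, against 0.0747 and 0.0241, and both 48 and 60 hours called 14 higher and 2 lower, against 0.292 and 0.0554. Across probe sets, which are not independent replicates, the differences at 36 and 48, 36 and 60, and 48 and 60 hours had correlations of 0.265, 0.502 and 0.137.

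Development between 36 and 60 hours gives the background against which the morphants can be read, and the mean array median of control embryos, before normalisation, was 2.72 at 36 hours and 1.92 at 60 hours. In control embryos cartilage genes rose and so did photoreceptor genes, while cell cycle genes fell, the last 2 lists not with an estimated correlation. The collagen gene col10a1a (Dr.4697.1.S1_at), a marker of forming bone and cartilage, rose by 8.63 ± 0.76 (SE, n = 3 arrays per group, limma adjusted p = 6.76e-07) from a mean of -1.89, too dim to fix the size, and the cartilage matrix gene matn1 rose 56.4-fold, by 5.82 ± 0.67. The photoreceptor genes crx, opn1sw1 and rho rose by 4.84 ± 0.75, 3.86 ± 0.70 and 3.67 ± 0.67 (limma adjusted p = 2.22e-04, 8.50e-04 and 9.28e-04). The hindbrain patterning gene hoxb1a fell by 4.92 ± 0.74, and exo1, an exonuclease gene of DNA repair, fell by 4.19 ± 0.62 (limma adjusted p = 1.74e-04 and 1.43e-04).

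In control embryos 2090 probe sets passed, 1113 higher and 977 lower, and in morphants 1376, 797 higher and 579 lower. Both called 1033 of them in the same direction and 0 in opposite directions, where independent lists, again no exact reference, would share 125. On the values as deposited 72 were higher and 1824 lower in controls and 29 and 137 in morphants, and with only the arrays compared 480 passed in controls. Of the 2090, 2039 had the same sign in the morphants, and over all probe sets tested the 2 changes had a correlation of 0.735. In morphants col10a1a, matn1 and crx also rose, from means at 36 hours of -1.45, -0.55 and -3.27, too dim to fix the size, and rho rose by 2.45 ± 0.67, while opn1sw1 differed by 1.34 ± 0.70 (limma adjusted p = 0.258) and hoxb1a by -1.76 ± 0.74 (limma adjusted p = 0.144). Other genes that rose in controls were otx5, ncam2, slc6a1a, gng13b and ckmt2a, by 4.52, 4.07, 3.97, 3.88 and 3.59. Others that fell were sox19b, casp8ap2, rad9a, klf1, ucp3, her2 and desi1b, by 3.88, 3.48, 3.36, 3.28, 3.16, 2.95 and 2.84. The protease gene ctslb fell by 3.13 ± 0.27, but of its 8 other probe sets 2 had the opposite sign, 1 of them called. By steps, control embryos had 2625 probe sets past the threshold between 36 and 48 hours and 3073 between 48 and 60 hours, and morphants 1824 and 111. Tested directly, the change between 48 and 60 hours differed between the kinds of embryo for 1 probe set. Over that step the mean array medians before normalisation went from 3.81 to 1.92 in controls and from 3.12 to 2.43 in morphants. The steps were not tried under the alternatives, so these counts do not show that morphant development slowed.

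Of the gene lists, 10 passed in control development. Cell cycle genes fell (19 of 24 fallen, 21 adjusted over the list alone, median -0.85, adjusted p = 3.65e-11, and adjusted p = 0.125 with an estimated correlation). Cartilage and bone genes rose (6 of 10 risen, 7 risen and 1 fallen adjusted over the list alone, median 1.22, adjusted p = 6.66e-05). Neuronal genes rose (7 of 14, and 7 adjusted over the list alone, median 0.79, adjusted p = 0.00148, and adjusted p = 0.0884 with an estimated correlation). Glia and neural progenitor genes fell (8 of 17 fallen and 2 risen, 10 and 2 adjusted over the list alone, median -0.45, adjusted p = 0.00148). Matrix genes rose (6 of 11, 7 adjusted over the list alone, median 0.47, adjusted p = 0.00148). Skeletal muscle genes rose (9 of 19 risen and 1 fallen, also adjusted over the list alone, median 0.31, adjusted p = 0.00211, and adjusted p = 0.0617 with an estimated correlation). Photoreceptor genes rose (7 of 13 risen and 3 fallen, also adjusted over the list alone, median 1.58, adjusted p = 0.00387, and adjusted p = 0.171 with an estimated correlation). The lists for glycolysis, oxidative phosphorylation and endocrine pancreas were higher (medians 0.57, 0.25 and 0.93, with 4, 2 and 3 genes risen, and 4, 4 and 3 adjusted over the list alone). They had an adjusted p of 5.35e-04, 0.00847 and 0.0345, and an adjusted p of 0.0884, 0.496 and 0.256 with an estimated correlation.

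Morphant development also passed for 10 lists. Cell cycle genes fell (16 of 24, 20 adjusted over the list alone, median -0.72, adjusted p = 1.88e-11, and adjusted p = 0.137 with an estimated correlation), and so did glia genes (10 of 17 fallen and 1 risen, 11 and 3 adjusted over the list alone, median -0.94, adjusted p = 1.30e-05). Neuronal genes (8 of 14, and 8 adjusted over the list alone, median 0.94, adjusted p = 1.30e-05), cartilage genes (5 of 10, and 5 adjusted over the list alone, median 0.56, adjusted p = 4.83e-04) and matrix genes (5 of 11, and 5 adjusted over the list alone, median 0.42, adjusted p = 0.00702) rose. Photoreceptor genes rose (5 of 13 risen and 2 fallen, 6 and 3 adjusted over the list alone, median 1.34, adjusted p = 0.0319, and adjusted p = 0.270 with an estimated correlation). The lists for glycolysis, oxidative phosphorylation, heat shock and endocrine pancreas were higher (medians 0.47, 0.25, 0.30 and 0.95, with 3, 3, 3 and 3 genes risen and 1 heat shock gene fallen). Adjusted over the list alone, 6, 3, 7 and 3 of their genes rose and 2 heat shock genes fell. They had an adjusted p of 1.57e-04, 0.00702, 0.0282 and 0.0282, and an adjusted p of 0.0809, 0.331, 0.350 and 0.236 with an estimated correlation. The count of morphant probe sets was 166 on the values as deposited, and it was 843, 911, 850 and 839 without morphant array 1 or 2 of 36 hours or morphant array 2 or 3 of 60 hours.

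A general shift of the morphants along this developmental course was not detected, but the test could not exclude one. At each time the difference between morphants and controls was regressed, across 11626 probe sets, on a control developmental change measured on other arrays. The mean slope was 0.0415, where a slope over 0 points to later stages, and the permutation p was 0.555 (8000 relabellings of the arrays within times, two-sided). The slopes at 36, 48 and 60 hours were -0.0859, 0.0742 and 0.136, with exact permutation p-values of 0.700, 0.2 and 0.400, where 3 arrays against 3 cannot give less than 0.1. These relabellings ignore pairs of same-numbered arrays. At 48 hours every such pair differed upwards, by 0.0569 to 0.0914. Swaps within pairs gave a permutation p of 0.25 there, the smallest possible, and of 0.523 for the mean slope. The mean slope turned to -0.0601 on the probe sets that changed in control development, and to -0.0181 without control array 2 of 36 hours. The control arrays of 48 hours enter the control changes used at 36 and at 60 hours with opposite signs. Control embryos had 2625 and 3073 probe sets called from 36 to 48 and from 48 to 60 hours, more than the 2090 from 36 to 60 hours. An offset of the 48-hour arrays would push the slopes at 36 and 60 hours apart, so the mean slope does not measure stage alone.

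The authors' own lists of higher and lower probe sets at each time, drawn from the same arrays and so no independent evidence, were compared with these differences. The lists hold probe sets with large differences on these arrays, which largely fixes the sign. All 447 listed probe sets that were tested had the same sign here, and 59 of them, 13.2%, passed the threshold. The filter had left out 497 of the 803 in the largest list, and without it 789 of 793 found had the same sign. In the authors' full table for 48 hours, 6107 probe sets had a probability of being higher in morphants under 0.2 and 162 one over 0.8. At 60 hours 370 were under 0.2 and 2776 over 0.8, and at 36 hours, in a table of 12648 probe sets against 15617 at the other times, 925 and 175.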

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

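The tests of how gene lists differ between times and the test of the authors' 48-hour table were chosen after the results were seen.

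The effect of the morpholino differed between times for 3 genes. For hbbe3 the morphant difference went from -0.08 to 1.5 between 36 and 60 hours (limma adjusted p = 0.0179, over the alternatives from 1.94e-06 to 0.626). For krt1-19d it was 1.23, 4.19 and -1.08 at the 3 times (limma adjusted p = 0.0179, over the alternatives from 1.15e-06 to 0.731), and for krt15 -2.84, 1.51 and -1.0 (limma adjusted p = 0.0180, over the alternatives from 1.97e-04 to 0.642). Of 100 splits of the arrays within times, 8, the real one included, gave as many, with a real value of 3 and a highest other of 31. All 7 others kept the real groups at 1 or 2 times, as they were or turned, so they carried the morpholino's own effect into this test. The one with 31 turned them at 60 hours but not at 48. The splits are no reference for chance here, which stays open, and in the 67 that kept the real groups at no time the highest count was 1.

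Among gene lists, the erythroid list had a higher morphant difference at 60 than at 36 hours (camera adjusted p = 0.00594 over 90 tests of list differences, medians -0.04, 0.20 and 0.10 at 36, 48 and 60 hours), while 48 against 36 hours did not pass (adjusted p = 0.0624). With an estimated correlation that list was past the threshold at no single time. The ATF4 target list had a higher difference at 48 than at 36 hours and at 60 than at 36 hours (adjusted p = 0.00813 for both, medians 0.17, 0.50 and 0.47). With an estimated correlation camera called the ATF4 list at 48 hours but not at 36 or 60 hours (adjusted p = 0.612 and 0.174). The differences between times were tested with the preset correlation only.

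Sterol synthesis genes were higher in the morphants at all 3 times. With the array median as a covariate 6 of 6 genes kept their call on average, msmo1 with 3.17 ± 0.28 instead of 3.20 ± 0.32. The median differences of morphants and controls (0.30, -0.69 and 0.50 at 36, 48 and 60 hours) nearly cancel on average. The covariate could therefore hardly move these values, and the kept calls do not decide on brightness. An effect that follows brightness would turn its sign at 48 hours, but the list medians were 1.47, 2.44 and 1.82. They argue against brightness in 1 direction as the whole cause. Embryos at another of the 3 stages sampled would keep the genes within the range of the control means. Above the highest control mean by over 2 standard errors at both 48 and 60 hours lay 4 of 6 genes, msmo1 by 2.99 and 2.72. They were msmo1, hmgcs1, fdps and insig1. The last encodes a sterol-sensing protein and not an enzyme, and only the authors' lists name the probe set used for it. A peak between the times sampled was not measured, so a stage between them stays open. For cyp51 (1.62 and 1.24 above, SE 0.91) and acat2 (-0.16 and 0.02, SE 0.19) a difference in stage stays open. Loss of the circulation, rather than the injection itself or a stage between or outside the times sampled, may raise sterol synthesis. This hypothesis was not tested, since the series has 1 morpholino against troponin T2 and the labels differ on whether the controls were injected. Arrays of embryos whose heart was stopped in another way, against injected controls, would test it.

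Photoreceptor and retina genes were lower in the morphants. With the array median as a covariate 8 of 8 called genes kept their call on average, among them opn1sw1 with -2.40 ± 0.37 instead of -2.43 ± 0.40. As for the sterol genes, the covariate could hardly move the average, so the kept calls do not decide on brightness. The list medians were -1.06, -0.69 and -1.93 at 36, 48 and 60 hours, while the difference of the array medians turned its sign at 48 hours. Under a general developmental delay other developmental genes would be shifted too. The slope on control development was -0.20 in the retina list (permutation p = 0.0015) and -0.0525 in 2080 other probe sets that change in control development (permutation p = 0.347), which is 0.0481 from the bound of -0.101 set for a general delay and within 2 SD of the permutations (0.101). In control development 7 of the 13 retina genes rose and 3 fell, and a delay alone would leave those 3 higher in the morphants. On average all 13 had a negative difference, but 5 of them did not pass. At 36 and 60 hours 1 and 2 of the 13 were positive. A delay of the whole embryo and a change in the eye cannot be told apart on these arrays. The slopes vary too much with 3 arrays per group, the 48-hour control arrays enter them with opposite signs, and few genes of the list fall in development.

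The authors' full table for 48 hours had 97.4% of its probe sets beyond a probability of 0.2 or 0.8 on the lower side. With no normalization between the arrays as the source of this excess, the side with more probe sets would follow the brightness of the arrays at each time. It did at 2 of 3 times, at 48 hours, where the morphant medians lay 0.69 below the controls', and at 60 hours, where they lay 0.50 above and 11.8% were lower. At 36 hours they lay 0.30 above and 84.1% were lower, in a table of 12648 probe sets against 15617 at the other times. With the values as deposited, 31.7%, 96.4% and 4.42% of the probe sets at an unadjusted p under 0.05 were lower in the morphants at 36, 48 and 60 hours. Quantile normalisation evens out the 2 sides whatever the cause, so the balance after it was not used. The medians at 48 hours were 3.86, 2.79 and 2.71 in morphant arrays 1, 2 and 3, and 3.86, 3.86 and 3.72 in the control arrays. The gap thus came from morphant arrays 2 and 3 and was not shared by morphant array 1. No normalization between the arrays and a real fall of most transcripts in some samples cannot be told apart at 48 hours. The table of 36 hours is not like the others, and no value here gives the amount of transcript per embryo.

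Other splits of the arrays gave the following. On average over the times chance is excluded for the count of probe sets, with a real value of 559 and a highest other of 29. For the count of lists on average, 4 of 100 splits, the real one included, gave as many, with a real value of 7 and a highest other of 7. That is under the share of 0.05 set for excluding chance, but only since probe sets with conflicting names were left unnamed after the results were seen. The share rests on a few names and on 100 splits drawn at random, so chance is not firmly excluded for the count of lists. Within a time the 6 arrays have 10 splits, too few to exclude chance or not, with real values of 21, 66 and 107 probe sets at 36, 48 and 60 hours and highest others of 7, 0 and 42. For lists the real values were 5, 6 and 5, the highest others 4, 5 and 7 and the medians of the others 2, 1 and 3. Lists thus passed under other groupings too, so single list calls with the preset correlation can be too liberal. The splits are as few for development, with a real value of 1376 and a highest other of 0 in morphants and a real value of 2090 and a highest other of 2427 in controls. That split set control array 1 of 36 hours and control arrays 1 and 2 of 60 hours, with medians of 1.48, 2.14 and 1.19, against 3.30, 3.38 and 2.45. It parts the arrays by brightness, but control array 1 of 36 hours was also closest to an array of 60 hours (correlation 0.849). Brightness, stage and that array cannot be told apart in it. With the real groups 2521 probe sets passed with the array median as a covariate. The split at 60 hours with 42 probe sets set medians of 1.19 to 2.19 against 2.45 to 2.56.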

How the results depend on the processing

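Array quality weights, the array median as a covariate, swaps within pairs, and leaving out the 2 dimmest arrays, 36 hours, the retina list or names were chosen after the data were seen. The sterol list kept its direction and its call at every time and on average under every single alternative run for lists. The retina list did so at 48 and 60 hours and on average. With the names left out and an estimated correlation together, sterol at 36 hours (adjusted p = 0.0896) and retina and ATF4 at 48 hours (adjusted p = 0.0518 and 0.0503) did not pass. Of 110 calls of named genes, 93 remained with arrays centred on their medians and 28 on the values as deposited. Of 23 list calls, 8 remained with an estimated correlation, 16 on the values as deposited, 18 with arrays centred on their medians and 23 without the names that only the authors' lists give. Of counts under an alternative, 168 of 273 were within 1.5 times the value reported. Of values of single genes 3463 of 4091 kept their direction and side of the threshold, 448 fell below it and 122 rose past it, and of lists 2376 of 2666 did so, 58 fell below and 87 rose past. In simulated arrays a log2 change of 1 was recovered at single times in 20.7% of cases for probe sets under the median level and 71.4% over it. The noise simulated there was independent between probe sets and alike on all arrays. Except where stated, the cause of a change was not tested.

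On the values as deposited, whose arrays differ in brightness, the counts were 0 at 36 hours (limma, 244 at an unadjusted p under 0.05), 5 at 48 hours, 1 at 60 hours, 6 on average (4 higher, 2 lower), 0 for a difference between times (508 at an unadjusted p under 0.05) and 166 for morphant development (29 higher, 137 lower, against 797 and 579). Control development had 72 higher and 1824 lower, against 1113 and 977. The ribosomal list at 36 hours turned down (adjusted p = 0.0283). With each array centred on its median the counts were 37 at 48 hours, 63 at 60 hours, 283 on average (183 higher, 100 lower, against 286 and 273) and 11 lists at 48 hours. The directions of cyt1 at 60 hours (-0.0556), the epidermis list at 36 hours (adjusted p = 0.940) and the skeletal muscle list at 48 hours (adjusted p = 0.0317) turned.

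With the 50th percentile filter 21 probe sets passed at 48 hours and 1 for a difference between times. Without the intensity trend 9 passed at 36 hours, 37 at 60 hours and 0 for a difference between times (856 at an unadjusted p under 0.05). With weights from the deposited standard errors the counts were 10, 11 and 680 at 36, 48 and 60 hours, the last with 343 higher and 337 lower against 79 and 28, then 1 for a difference between times and 2329 for morphant development, and on average 244 higher and 149 lower. With only the arrays compared, which leaves fewer arrays for the spread, they were 0 at 36 hours (627 at an unadjusted p under 0.05), 361 at 48 hours, 34 at 60 hours (17 higher, 17 lower) and 480 for control development. A minimum log2 difference of 1 gave 135 on average, 1167 for control and 758 for morphant development. With 1 probe set per named gene, which leaves fewer probe sets, the counts were 12 at 36 hours, 51 at 60 hours, 221 on average, 6 for a difference between times, and 563 and 397 for control and morphant development.

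With an estimated correlation 1, 3, 2 and 2 lists passed at 36, 48 and 60 hours and on average. With all probe sets of the members 3 passed at 36 hours and 11 on average. Array quality weights (up to 4.02) led to 736 probe sets at 48 hours, 4854 at 60 hours, 2745 on average, 2310 for a difference between times, 3521 and 3593 for control and morphant development, and 8 lists at 36 hours. With the array median as a covariate the counts were 52 at 36 hours, 175 at 48 hours, 1810 on average and 6 for a difference between times. Without the 2 arrays with the lowest medians they were 229 at 48 hours, 7 for a difference between times and 2195 for morphant development. Without 36 hours 11 lists passed on average.

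The replicate block of same-numbered morphant and control arrays gave 182 probe sets at 60 hours (141 higher, 41 lower), 1026 on average and 6 for a difference between times. It ended the calls of the ribosomal list at 48 hours (adjusted p = 0.0575) and the erythroid list at 60 hours (adjusted p = 0.0522), and 100 of 110 calls of named genes remained. All 3 pairs of 36 and of 48 hours and 2 of 3 at 60 hours had a correlation of their deviations over 0.1 (from -0.063 to 0.271), and 8 of 9 controls were closest to their own number. This hints that the numbers pair the arrays, which the labels do not say. Swaps within pairs gave a permutation p of 0.523 for the mean developmental slope and 0.25, the smallest 3 pairs give, at 48 hours, where every pair differed upwards.

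Leaving out 1 array gave from 12 to 293 probe sets at 36 hours, from 21 to 56 at 48 hours, from 10 to 456 at 60 hours, from 230 to 1551 on average, from 0 to 23 for a difference between times, from 1462 to 3133 for control development and from 839 to 1261 for morphant development. At 48 hours, without morphant array 1, 21 were higher and 24 lower, against 43 and 23. On average the count was 1551 without control array 3 of 36 hours and 339 and 345 without morphant arrays 1 and 2 of that time. It was 301 and 328 without control arrays 1 and 2 of 48 hours, and 354, 353 and 289 without morphant arrays 1, 2 and 3 of that time. Without control arrays 1, 2 and 3 of 60 hours it was 331, 289 and 1119, and without morphant arrays 1, 2 and 3 it was 1192, 230 and 264. For a difference between times it was 6 and 23 without control arrays 1 and 2 of 36 hours, 1 and 6 without control arrays 2 and 3 of 48 hours, 1 without morphant array 3 of 48 hours, 1 and 15 without control arrays 2 and 3 of 60 hours, and 0 in the 6 cases named with those calls (limma, from 627 to 1132 at an unadjusted p under 0.05). Lists ran from 3 to 7 at 36 hours (3 without morphant array 1), from 4 to 6 at 48 hours, from 5 to 7 at 60 hours and from 6 to 11 on average (11 without control array 1 of 36 hours). The mean developmental slope ran from -0.0181, without control array 2 of 36 hours, to 0.0727, and it was -0.0601 on the probe sets that change in control development (permutation p = 0.281). Alternatives not run were the deposited model values in place of the series values, which are the same. A fit of only the arrays compared was not run for any gene list. Nor was it run for the average and the difference between times, which use all arrays. The steps of development between 36, 48 and 60 hours had no alternatives.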

Other observations

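The genes and arrays of this part were singled out after their values were seen.

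Outside the lists that passed, single genes of other tissues changed on average over the times, with 9 arrays of each kind. Of the liver list, itih2, which encodes a chain of a plasma protease inhibitor, rose by 0.81 ± 0.14 (limma adjusted p = 0.00446). The plasminogen gene plg of the coagulation list rose by 0.72 ± 0.15 (limma adjusted p = 0.0138). Of the cartilage list, sox9b, a cartilage transcription factor gene, fell by 0.33 ± 0.09 (limma adjusted p = 0.0451). The liver gene itih3a.1 and the cartilage gene matn1 fell by 1.86 ± 0.46 and 1.46 ± 0.39 (limma adjusted p = 0.0271 and 0.0374), but only the authors' lists, chosen on these arrays, give their names, so they are no independent evidence of direction. The retinol-binding gene rbp2a of the intestine list fell by 0.91 ± 0.15 (limma adjusted p = 0.00188), and the synaptic gene snap25b fell by 0.47 ± 0.10 (limma adjusted p = 0.0114).

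Further single genes passed on average. The stress transcription factor gene atf3 rose by 0.83 ± 0.17 and the Notch ligand gene dla by 0.53 ± 0.11 (limma adjusted p = 0.0118 and 0.0125). The growth factor binding protein gene igfbp3 rose by 0.81 ± 0.21, the ferritin gene fth1a rose by 0.17 ± 0.05 and the metallothionein gene mt2 fell by 0.87 ± 0.24 (limma adjusted p = 0.0310, 0.0434 and 0.0486). The gene bmp4, of the epicardium and valve list that was not tested, rose by 1.06 ± 0.23 (limma adjusted p = 0.0162).

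The control array 1 of 36 hours stood apart. Its median deposited standard error was 0.82 and its closest array was morphant array 1 of 60 hours (correlation 0.849 across probe sets), while its lowest correlation within its group was 0.831. Arrays of the same group had correlations from 0.831 to 0.962, with a median of 0.948, and arrays of different groups a median of 0.875 and a highest of 0.965, between control and morphant arrays 3 of 36 hours. Of 18 arrays 6 were closest to an array of the other kind of embryo, among them all 3 controls of 36 hours.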
